A study of Homo sapiens with 23 samples.

How the data were processed

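RNA was measured in 23 libraries of 8 groups from 4 human breast cell lines, grouped by their sample titles: HMLER CD44low, 104Med and 104High, HCC38 CD44low, 104Med and 104Low, MCF7 and ZR751. Below, 104Med, 104High and 104Low stand for the CD44high groups with those labels. Per the labels' protocols, HMLER cells were grown in serum-free mammary epithelial medium with hydrocortisone, EGF, insulin and pituitary extract and the other lines in RPMI with fetal bovine serum, cells were harvested before confluence, and libraries were made with the TruSeq Stranded mRNA kit and sequenced in paired ends on a HiSeq instrument. RNA integrity numbers were above 9, per the labels. The series' design text and the sample descriptions name different kits for RNA isolation (RNeasy and miRNeasy Micro).

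The authors deposited a single table for the whole series with 28395 Entrez gene IDs and 23 columns. Its name speaks of FPKM, but its values are whole numbers whose library totals run from 4915395 to 19299296, so the deposited values were treated as raw counts of reads or fragments per gene, not normalised. The submitters' processing notes name edgeR and limma, with no version or role, and the GRCh38 build, while a sample description names hg19. The aligner, the counting program and its strand setting are not given in the sources used here. Because the build is in conflict, chromosomes are given without coordinates. Without a stated strand setting, overlapping and antisense genes stay uncertain, HRAS among them, since it overlaps LRRC56, and genes of close families can share reads. Symbols and chromosomes came from a RefSeq gene table, in which 27745 IDs matched and 650 did not. Genes without a match were tested and not named.

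The test planned before the data were examined was limma on log2(FPKM + 1). Since the file holds counts, the test that counts need took its place, and the FPKM thresholds of the plan were read as CPM. The groups, comparisons, gene lists, naming rule and most alternatives were likewise fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes with at least 1 CPM in at least 2 libraries of the fit were kept, libraries were scaled by TMM, and a quasi-likelihood model (glmQLFit in its legacy mode, with the default prior count of 0.125) was fitted with 1 coefficient per group and no further covariate. The 3 HMLER groups entered one fit, the 3 HCC38 groups another, all 6 groups of these lines another for the comparisons over both lines, and MCF7, ZR751 and both CD44low groups the last. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors were taken as the absolute log2 fold change over the square root of the F statistic. Printed CPM values use TMM factors over all 23 libraries. In comparisons over both lines, each line or group was weighted equally. A biological coefficient of variation of 0.2 was estimated in the HMLER fit and 0.135 in the HCC38 fit.

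Where every library of a side had 0 counts, a fold is given as a bound, computed against 3 counts over that whole side. With 1 to 3 counts, the ratio is given with its 95% counting interval. The text names genes by a rule with 3 parts. The first part is a set of markers named whatever their test: CD44, AR, ITGB4, CD24, EPCAM, CDH1, VIM, ZEB1, FN1, ESR1, FOXA1, GATA3, KRT14, KRT5, TP63, HRAS, TERT, FKBP5 and NR3C1. The second is the 6 called genes with the highest and the 6 with the lowest fold change among those with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the 2 sides. The condition on overlap was not applied to the difference between the lines. Clone-style and LOC names, small RNAs, pseudogenes, and mitochondrial and sex-specific genes were left out of this second part. The third is, for each list described, the 2 called members that rose most and the 2 that fell most with a mean of at least 1 CPM, or the most abundant members where fewer passed. Not every gene the rule gives is named.

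A total of 20 gene lists with 482 entries were written from general knowledge: androgen response, mesenchymal, epithelial junction, luminal, basal, oestrogen response, stem cell markers, TGF-beta, Wnt, interferon, inflammatory cytokines, proliferation, cholesterol synthesis, hypoxia and glycolysis, steroid enzymes, steroid receptors, keratinocyte differentiation, and markers of leukocytes, endothelial cells and fibroblasts as cell types a culture could also hold. Members that passed the test over all genes count as having risen or fallen, and counts adjusted over the list alone are given beside them, and are the same where none are given. Each list was tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and, as an alternative, a correlation estimated from the data, with p-values adjusted over the 20 lists of a comparison.

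The alternatives fixed before the data were examined were a pseudocount of 0.1 (run as limma on log2(CPM + 0.1)), no filter on low counts, median-ratio scaling, all 23 libraries in 1 fit, the replicate number as a block, leaving out each replicate in turn and the estimated correlation for lists. Added after the data were seen were limma on log2(CPM + 1), DESeq2 1.42.0 with its size factors, library totals without TMM, and mitochondrial genes left out. The procedure was tested on simulated data before use. In each simulation 67 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold, and the rest were left unchanged. In a simulation of HMLER 104Med against CD44low over 12096 genes, 7.46% of genes changed 1.5-fold, 47.8% of those changed 2-fold and 95.5% of those changed 4-fold were recovered, and 3.85% of the calls were false. For HCC38 104Med against CD44low over 13329 genes the shares were 26.9%, 67.2% and 98.5%, with 4.48% false calls. False calls made up 7.41% of calls for HMLER 104Med against 104High and 5.92% for HCC38 104Med against 104Low. The share was 7.69% for the difference between the lines, 6.59% over both lines and 7.14% for the luminal lines. In these further simulations the share of false calls thus lay above the level set by the adjusted threshold. No replicate pair of a group agreed within sampling noise (chi-square per degree of freedom from 5.81 to 159.6 over genes with at least 10 counts). No splicing, isoform or variant analysis was made, and the levels of sex-specific genes are not reported here.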

Results

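Polyadenylated RNA was sequenced in 23 libraries from 4 human breast cell lines. HMLER cells are human mammary epithelial cells transformed in sequence with hTERT, the SV40 early region and RAS. HCC38 is a triple-negative breast cancer line, and MCF7 and ZR751 are luminal, oestrogen receptor-positive lines. The sample titles divide HMLER cells into CD44low (n = 3), CD44high with 104Med (n = 3) and CD44high with 104High (n = 3), and HCC38 cells into CD44low (n = 2), CD44high with 104Med (n = 3) and CD44high with 104Low (n = 3). MCF7 and ZR751 were sequenced without such a division (n = 3 each). Total counts per library ranged from 4915395 (HMLER 104High replicate 3) to 19299296 (HMLER 104Med replicate 3). Levels are normalised CPM (counts scaled to a common library total), given as mean ± SD, and fold changes are log2 values ± SE, with Benjamini-Hochberg adjusted p-values from edgeR's quasi-likelihood test for genes and from camera for gene lists. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Counting intervals and lower bounds on a fold cover counting error only. Each gene below that passed the test between groups had every library of one side beyond every library of the other, except SERPINE1, EGLN3, KDR, AR and TERT in the comparison over both lines and SNAI1 in that of the luminal lines.

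The labels name CD44 and a marker called 104, which they do not spell out. ITGB4 encodes integrin β4, also known as CD104. CD44 RNA (Entrez gene 960, chromosome 11), which encodes the hyaluronan receptor, stood at 2461 ± 381 CPM in HMLER CD44low, 1512 ± 321 in 104Med and 3185 ± 321 in 104High. In HCC38 it stood at 655 ± 7.87 CPM in CD44low (n = 2), 460 ± 63.9 in 104Med and 363 ± 14.3 in 104Low, and in MCF7 and ZR751 at 33.2 ± 4.47 and 39.9 ± 0.927. In HCC38 the means of both CD44high groups thus lay below that of CD44low. The mean of HMLER 104Med lay below that of HMLER CD44low as well, and that of HMLER 104High lay above it. ITGB4 RNA (Entrez gene 3691, chromosome 17) was 929 ± 265 CPM in HMLER 104Med and 2397 ± 213 in 104High, and 29.6 ± 8.2 in HCC38 104Med and 8.89 ± 4.64 in 104Low, so its order followed the labels among the CD44high groups of each line. The CD44low groups had the highest ITGB4 levels of their lines, 6428 ± 257 in HMLER and 423 ± 49.1 in HCC38. AR, the androgen receptor gene (Entrez gene 367, chromosome X), stood at 17.4 ± 1.93 CPM in HCC38 104Med, 19.7 ± 3.2 in 104Low and 0.134 ± 0.0445 in CD44low, against 64.9 ± 8.14 in MCF7 and 45.5 ± 18.5 in ZR751. The 3 HMLER groups held 1, 2 and 3 AR counts in all, in CD44low, 104Med and 104High.

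**Figure D1:**
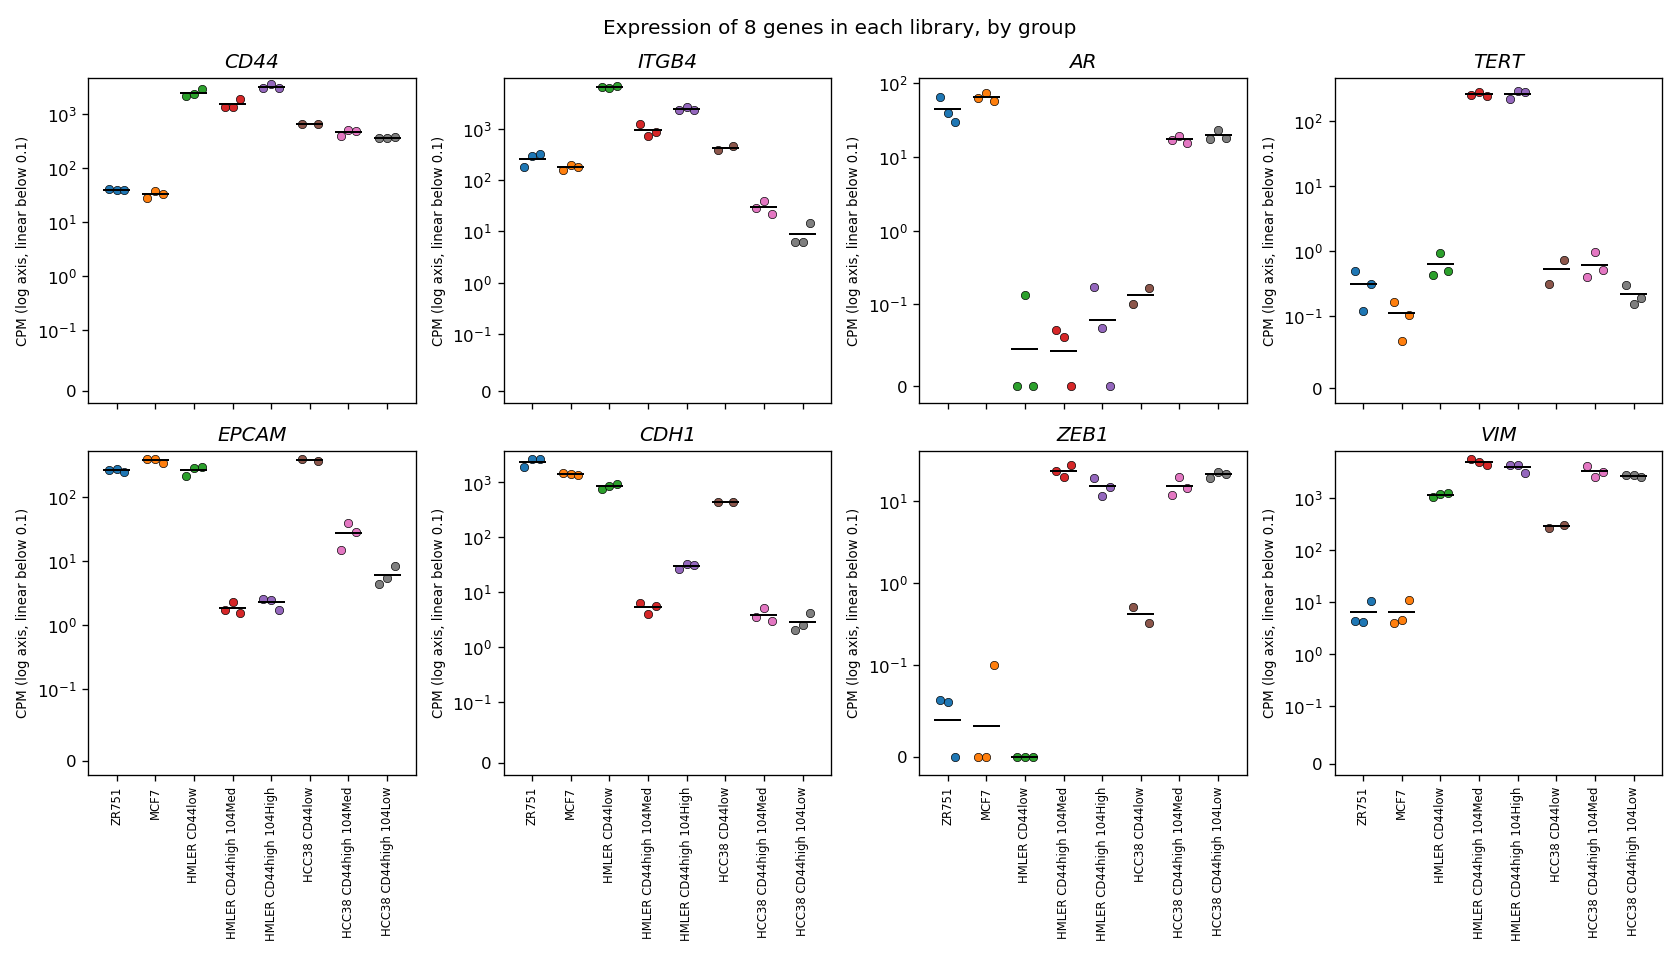
CPM of 8 genes in each library on a log axis that is linear below 0.1, with libraries as points and group means as bars. AR is near 0 in every HMLER library and in HCC38 CD44low, and TERT reaches a mean of 260 CPM in HMLER 104Med against 0.626 in HMLER CD44low.

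Genes encoded by the mitochondrial genome took a larger share of counts in the CD44low groups. The share was 27.6% ± 10.9 in HMLER CD44low, where replicate 2 had 39.97%, against 8.04% ± 4.45 in 104Med and 8.12% ± 1.66 in 104High. In HCC38 it was 17.1% ± 4.28 in CD44low, 10.3% ± 3.16 in 104Med and 7.16% ± 0.551 in 104Low. MCF7 and ZR751 had 8.74% ± 1.51 and 8.28% ± 1.16. No test was run on these shares, and they accompany every comparison with CD44low below.

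**Figure D2:**
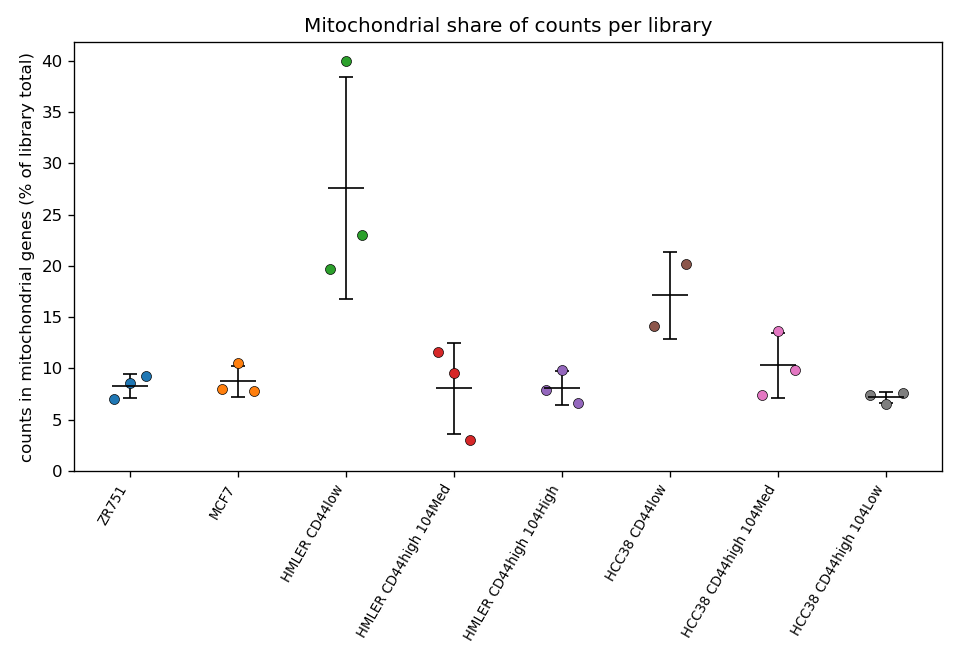
Share of each library's counts in mitochondrial genes, in % of the library total, with libraries as points and mean ± SD as bars. HMLER CD44low averages 27.6% and HMLER 104Med 8.04%.

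The first comparison asked how HMLER 104Med cells differed from HMLER CD44low cells (n = 3 each). Genes of epithelial cell junctions were lower in 104Med. CDH1, which encodes E-cadherin, was at 5.33 ± 1.23 CPM in 104Med and 855 ± 100.3 in CD44low (log2 fold change -7.41 ± 0.25, adjusted p = 3.36e-10). EPCAM, an epithelial adhesion gene, changed by -7.23 ± 0.25, adjusted p = 3.36e-10. ZEB1 and ZEB2, repressors of epithelial genes, had no counts in any CD44low library and were at least 282-fold and at least 150-fold higher in 104Med (adjusted p = 3.86e-08 and 8.7e-08). VIM, which encodes the intermediate filament vimentin, was higher by 2.02 ± 0.22, adjusted p = 8.83e-06, and DCN, which encodes the matrix proteoglycan decorin, by 10.22 ± 0.36, adjusted p = 3.36e-10. TERT, the telomerase catalytic subunit gene and also one of the transforming constructs, was at 260 ± 23.3 CPM in 104Med and 0.626 ± 0.282 in CD44low, where the 3 libraries held 20 counts in all (8.73 ± 0.29, adjusted p = 3.36e-10). HRAS was higher by 1.35 ± 0.29, adjusted p = 0.00245, and counts of the endogenous and introduced copies of TERT and HRAS were not separable here.

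By list, the epithelial junction genes moved most evenly in HMLER 104Med against CD44low: 0 rose and 32 fell of 33 measured, with the same counts when adjusted over the list alone, a median log2 fold change of -3.98 and an adjusted p = 4.26e-23 (adjusted p = 0.00259 with an estimated correlation). Of the basal epithelial genes 1 rose and 23 fell of 25 measured (the same adjusted over the list alone), with adjusted p = 2.98e-12 and adjusted p = 0.0211 with an estimated correlation. KRT14 and KRT5, keratins of basal cells, changed by -8.08 ± 0.39 and -4.84 ± 0.27, TP63, a basal transcription factor gene, by -4.74 ± 0.36 and ITGB4 by -2.87 ± 0.24. MYLK, a myosin kinase gene, was the basal member that rose (1.47 ± 0.18). Keratinocyte differentiation genes fell as well, 0 rose and 11 fell of 14 measured, among them SPRR1B, a cornified envelope gene at least 398-fold lower with no counts in 104Med. The fitted median of that list was -4.72, and -4.39 with undetected genes at their bound (adjusted p = 1.06e-06, and adjusted p = 0.164 with an estimated correlation). Among mesenchymal genes 24 rose and 2 fell of 35 measured, with a median of 1.80 (adjusted p = 9.58e-12, and adjusted p = 0.0575 with an estimated correlation). Markers of endothelial cells moved with them: 5 rose and 1 fell of 6 measured, including ROBO4 (4.78 ± 0.19) and PECAM1 (4.51 ± 0.42), with adjusted p = 0.000686 and adjusted p = 0.0575 with an estimated correlation. The fitted median of the endothelial list was 3.69, and 3.12 with undetected genes at their bound.

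In all, 4969 of 12391 genes tested passed the threshold between HMLER 104Med and CD44low, 2236 higher and 2733 lower in 104Med, and 2661 of them changed at least 2-fold. With library totals in place of TMM scaling the split was 4944 higher and 1206 lower, and in a fit of all libraries 3458 genes were higher. The largest decreases included SLC1A6, a glutamate transporter gene at least 1528-fold lower, and A2ML1, a protease inhibitor gene at least 308-fold lower, neither of which had counts in 104Med. Among the increases were RTN1, a reticulon gene (9.92 ± 0.46), and GLIS1, a zinc finger gene with no counts in CD44low and at least 86.7-fold higher. The glucocorticoid receptor gene NR3C1 (0.33 ± 0.16, adjusted p = 0.13), the steroid-responsive chaperone gene FKBP5 (0.57 ± 0.23, adjusted p = 0.065) and the fibronectin gene FN1 (0.70 ± 0.43, adjusted p = 0.221) did not pass. Over the alternatives the adjusted p ranged from 0.00319 to 0.203 for FKBP5, which passed in 10 of them, from 0.00762 to 0.283 for NR3C1, which passed with library totals (0.00762), in a fit of all libraries (0.0224) and without CD44low replicate 1 (0.0462), and from 0.0376 to 0.92 for FN1, which passed with library totals (0.0376). CD44 changed by -0.79 ± 0.21, adjusted p = 0.0101, a call lost with library totals (adjusted p = 0.361) and without 104Med replicate 1 (0.0583), 104Med replicate 2 (0.0594) or CD44low replicate 3 (0.0585), over a range of 0.00047 to 0.361 across alternatives.

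HMLER 104High cells were compared with the same CD44low libraries (n = 3 each). CDH1 (-4.86 ± 0.22, adjusted p = 3.4e-09) and EPCAM (-6.82 ± 0.25, adjusted p = 1.15e-09) were again lower, and VIM was higher (1.72 ± 0.22, adjusted p = 5.2e-05). FN1, which encodes fibronectin, rose from 8796 ± 2338 to 62681 ± 12057 CPM (2.82 ± 0.46, adjusted p = 0.000389). ZEB1 was at least 177-fold higher and TERT, at 264 ± 36.8 CPM, was higher by 8.81 ± 0.29, adjusted p = 9.13e-10. KRT14 (-4.04 ± 0.32), KRT5 (-3.08 ± 0.25) and ITGB4 (-1.45 ± 0.23) fell, and CD44 RNA did not pass (0.34 ± 0.21, adjusted p = 0.24). NR3C1 was higher by 0.52 ± 0.17, adjusted p = 0.027, a call lost without 104High replicate 1 (adjusted p = 0.0817) or 3 (0.0688) and without CD44low replicate 2 (0.103) or 3 (0.104), over a range of 0.00402 to 0.104 across alternatives. HRAS (0.59 ± 0.31, adjusted p = 0.164) did not pass, but did with library totals (adjusted p = 0.0423) and without CD44low replicate 2 (0.0376), over a range of 0.0376 to 0.461.

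Epithelial junction genes (0 rose and 31 fell of 33 measured, the same adjusted over the list alone) had adjusted p = 2.62e-22, and adjusted p = 0.00286 with an estimated correlation. For mesenchymal genes the counts were 25 and 0 of 35 (26 and 0 adjusted over the list alone), with adjusted p = 3.32e-16 and adjusted p = 0.0281 with an estimated correlation. Markers of endothelial cells moved with them (5 rose and 0 fell of 6 measured, adjusted p = 7.33e-05, and adjusted p = 0.0334 with an estimated correlation), as did fibroblast markers (5 rose and 2 fell of 11 measured, adjusted p = 0.0396, and adjusted p = 0.331 with an estimated correlation). The fibroblast call was also lost with library totals (adjusted p = 0.0829), in a fit of all libraries (0.0569) and without 104High replicate 2 (0.0565), over a range of 0.00214 to 0.331. Interferon-stimulated genes fell in 104High, 0 rose and 18 fell of 21 measured (1 and 18 adjusted over the list alone). MX1, an antiviral GTPase gene, changed by -3.43 ± 0.28 and HERC5, an interferon-induced ligase gene, by -3.06 ± 0.33. That list had a median of -2.22, adjusted p = 4.05e-09 and adjusted p = 0.0281 with an estimated correlation. In 104Med against CD44low the same list had 2 that rose and 11 that fell of 21, a median of -1.19, adjusted p = 0.00322 and adjusted p = 0.172 with an estimated correlation. Basal genes (1 rose and 16 fell of 25 measured) had adjusted p = 5.04e-06, and adjusted p = 0.0564 with an estimated correlation. Of 12391 genes tested, 4066 passed, 1909 higher and 2157 lower in 104High, and 2560 higher and 1284 lower with library totals. These tests share their CD44low libraries with those of 104Med, so the lists are not independent evidence.

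Set directly against each other, HMLER 104Med and 104High cells (n = 3 each) differed in basal and interferon genes. KRT14 was 26.1 ± 12.9 CPM in 104Med and 416 ± 24 in 104High (-4.05 ± 0.32, adjusted p = 7.02e-06). COL17A1, a hemidesmosome collagen gene, differed by -4.35 ± 0.41, adjusted p = 3.35e-05, ITGB4 by -1.42 ± 0.23, adjusted p = 0.0021, TP63 by -2.51 ± 0.35, adjusted p = 0.000741 and CD44 by -1.13 ± 0.22, adjusted p = 0.00577, all lower in 104Med. CDH1 was lower as well (-2.55 ± 0.21, adjusted p = 9.28e-06), while TERT (-0.08 ± 0.18, adjusted p = 0.843), ZEB1 (0.58 ± 0.23, adjusted p = 0.144) and VIM (0.30 ± 0.22, adjusted p = 0.439) did not pass, ZEB1 with adjusted p = 0.0448 in a fit of all libraries (range 0.0448 to 0.401). SLFN11, a gene of the DNA damage response, was higher in 104Med (3.35 ± 0.26, adjusted p = 6.42e-06), as was the calprotectin gene S100A8 (3.49 ± 0.50, adjusted p = 0.000944). Basal genes (0 rose and 17 fell of 25 measured, 1 and 18 adjusted over the list alone) had adjusted p = 4.77e-14, and adjusted p = 0.025 with an estimated correlation. Interferon-stimulated genes (9 rose and 0 fell of 21 measured, 14 and 0 adjusted over the list alone) included OASL (1.82 ± 0.22) and IFIT1 (1.74 ± 0.29), both induced by interferon. Their test gave adjusted p = 9.44e-11, and adjusted p = 0.025 with an estimated correlation.

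Between HMLER 104Med and 104High, 1348 of 12391 genes passed, 389 higher and 959 lower in 104Med, and 937 higher and 280 lower with library totals. In a fit of all libraries 2455 passed, 1147 higher and 1308 lower, and without the filter 627 genes were higher. With 1 library left out, and so fewer on its side, the count was 772, 661 and 709 without 104High replicates 1, 2 and 3. It was 624 and 658 without 104Med replicates 1 and 2, but 1544 without 104Med replicate 3. FN1 (-2.12 ± 0.45, adjusted p = 0.00962) lost its call without 104Med replicate 1 (log2 fold change -1.84, adjusted p = 0.0605, range across alternatives 2.57e-08 to 0.0605).

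In HCC38, 104Med cells (n = 3) were compared with CD44low cells (n = 2). AR was at 17.4 ± 1.93 CPM in 104Med and 0.134 ± 0.0445 in CD44low, where both libraries held 4 counts in all (7.02 ± 0.35, adjusted p = 9.09e-10). ESR2, which encodes oestrogen receptor β, rose with it (5.37 ± 0.54, adjusted p = 1.34e-06), and ESR1 had 1 count in 104Med and 1 in CD44low. TMPRSS2, an androgen-regulated protease gene, fell to 3 counts in all, a ratio of 9.43e-04 (95% counting interval 1.94e-04 to 0.00276). CDH1 (-6.83 ± 0.25), EPCAM (-3.77 ± 0.30) and KRT5 (-7.46 ± 0.36) were lower, and VIM (3.51 ± 0.24) and ZEB1 (5.10 ± 0.33) were higher. The growth factor genes MSTN (myostatin) and GDNF had no counts in CD44low and were at least 1128-fold and at least 377-fold higher. KLK5, a skin protease gene, changed by -11.48 ± 0.32, and the related protease gene KLK10 was at least 769-fold lower with no counts in 104Med. Apart from ESR1, which was too low to test, each of these genes passed, with adjusted p-values from 9.65e-12 for KLK5 to 1.34e-06 for ESR2.

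Epithelial junction genes in HCC38 104Med (1 rose and 36 fell of 38 measured, 1 and 37 adjusted over the list alone) had a median of -4.42 and adjusted p = 2.25e-17. Mesenchymal genes (32 rose and 2 fell of 36 measured) had a median of 2.40 and adjusted p = 4.22e-11, and CDH11, a mesenchymal cadherin gene, was among those that fell (-4.81 ± 0.31). Of the keratinocyte differentiation genes 0 rose and 9 fell of 11 (0 and 10 adjusted over the list alone, adjusted p = 4.72e-06). For each of these lists the adjusted p = 0.159 with an estimated correlation. Fibroblast markers moved with the mesenchymal list, with which they share 8 of their 14 genes: 8 rose and 1 fell of 10 measured (adjusted p = 0.000561, and adjusted p = 0.384 with an estimated correlation). COL3A1, a fibrillar collagen gene on both lists, rose by 7.74 ± 0.57. Leukocyte markers (2 rose and 1 fell of 3 measured, adjusted p = 0.416) and endothelial markers (1 rose and 2 fell of 3 measured, adjusted p = 0.416) did not pass. In all, 7148 of 13609 genes passed, 3464 higher and 3684 lower in 104Med, and 4338 higher and 3046 lower with library totals. CD44 (-0.51 ± 0.15, adjusted p = 0.0124) lost its call with library totals (adjusted p = 0.0524) and without CD44low replicate 1 (0.0595) or 2 (0.0517), over a range of 0.00215 to 0.0595.

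HCC38 104Low cells (n = 3) were compared with the same CD44low libraries (n = 2). AR was at 19.7 ± 3.2 CPM (7.20 ± 0.35, adjusted p = 6.46e-10), EPCAM changed by -5.93 ± 0.34, adjusted p = 3.87e-09, ITGB4 by -5.58 ± 0.32, adjusted p = 3.29e-09 and CD44 by -0.85 ± 0.15, adjusted p = 0.000332. COL3A1 was higher by 11.33 ± 0.62, adjusted p = 2.39e-09, FN1 by 2.99 ± 0.31, adjusted p = 1.93e-06, and LUM, which encodes lumican and had no counts in CD44low, at least 764-fold. TMPRSS2 changed by -9.44 ± 0.33. FKBP5, an androgen- and glucocorticoid-responsive gene, changed by 0.45 ± 0.13, adjusted p = 0.00891, a call lost without CD44low replicate 2 (adjusted p = 0.135) and in a fit of all libraries (0.104), over a range of 0.00153 to 0.135. Mesenchymal genes (32 rose and 2 fell of 36 measured, 33 and 2 adjusted over the list alone) and epithelial junction genes (0 rose and 37 fell of 38 measured, 0 and 38 adjusted over the list alone) had adjusted p = 3.73e-15 and 1.09e-20, and adjusted p = 0.118 for both with an estimated correlation. Fibroblast markers (9 rose and 0 fell of 10 measured, median 3.45) moved with the mesenchymal list (adjusted p = 3.19e-06, and adjusted p = 0.268 with an estimated correlation). Of 13609 genes, 7119 passed, 3492 higher and 3627 lower, and 4653 higher and 2732 lower with library totals.

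HCC38 104Med and 104Low cells (n = 3 each) were compared directly as well. EPCAM was at 27.2 ± 12.1 CPM in 104Med and 6.1 ± 2.09 in 104Low (2.16 ± 0.30, adjusted p = 0.000406), and ITGB4 was higher in 104Med as well (1.74 ± 0.28, adjusted p = 0.00102), as was the tight junction gene CLDN3 (2.38 ± 0.28, adjusted p = 0.00013). FN1 (-2.12 ± 0.26, adjusted p = 0.000146), COL3A1 (-3.60 ± 0.34, adjusted p = 2.07e-05) and ENPP2, which encodes autotaxin (-4.52 ± 0.38, adjusted p = 1e-05), were lower in 104Med. AR (-0.18 ± 0.15, adjusted p = 0.476), CDH1 (0.43 ± 0.26, adjusted p = 0.295), VIM (0.27 ± 0.18, adjusted p = 0.359), ZEB1 (-0.45 ± 0.18, adjusted p = 0.107) and CD44 (0.34 ± 0.14, adjusted p = 0.119) did not pass. ZEB1 passed without the filter (adjusted p = 0.0462) and without 104Med replicate 2 (0.00483), over a range of 0.00483 to 0.311, and CD44 without 104Med replicate 1 (0.0329), over a range of 0.0329 to 0.346. Mesenchymal genes (0 rose and 21 fell of 36 measured, 0 and 26 adjusted over the list alone) had adjusted p = 1.6e-12, and adjusted p = 0.365 with an estimated correlation. Epithelial junction genes (12 rose and 0 fell of 38 measured, 17 and 0 adjusted over the list alone) had adjusted p = 1.01e-05, and adjusted p = 0.572 with an estimated correlation. Fibroblast markers (0 rose and 9 fell of 10 measured) moved with the mesenchymal list (adjusted p = 1.64e-07, and adjusted p = 0.474 with an estimated correlation). In all, 1840 of 13609 genes passed, 830 higher and 1010 lower in 104Med, and 604 higher and 1222 lower with library totals. In a fit of all libraries 1202 passed, of which 506 were higher. The count was 977, 951 and 1200 without 104Low replicates 1, 2 and 3, 3737 without 104Med replicate 2 and 815 without 104Med replicate 3.

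**Figure D3:**
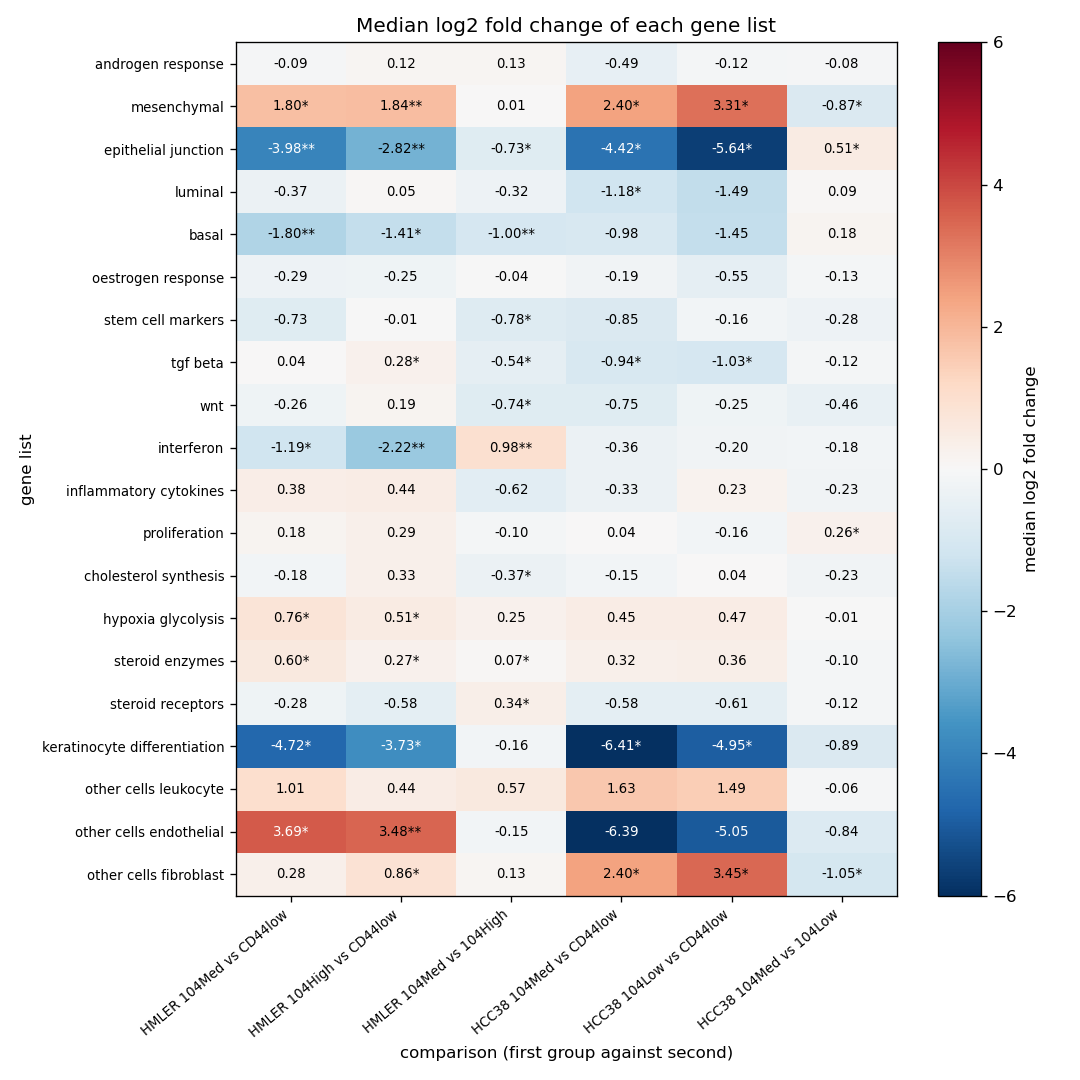
Median fitted log2 fold change of each of the 20 gene lists (vertical axis) in the 6 comparisons within HMLER and HCC38 (horizontal axis), with 1 star for an adjusted p under 0.05 with the preset correlation and a second where an estimated correlation also gives one. Epithelial junction genes have medians of -3.98 and -4.42 in the 104Med groups against CD44low.

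CD44high and CD44low cells were also compared over both lines, with the 2 CD44high groups of each line averaged. ZEB2 rose from 1 count in the 5 CD44low libraries, a ratio of 570 (95% counting interval 102 to 22517), and DCN by 6.12 ± 0.22, adjusted p = 6.45e-15. SERPINE1, which encodes plasminogen activator inhibitor 1, was higher by 4.30 ± 0.27, adjusted p = 4.3e-11. CDH1 (-6.55 ± 0.14, adjusted p = 1.68e-18), KRT5 (-5.39 ± 0.18, adjusted p = 1.34e-15) and GRHL2, an epithelial transcription factor gene (-8.00 ± 0.20, adjusted p = 1.48e-17), were lower. All 39 measured epithelial junction genes fell (adjusted p = 4.59e-28, and adjusted p = 0.00355 with an estimated correlation). Mesenchymal genes (33 rose and 1 fell of 38 measured, 34 and 1 adjusted over the list alone) had adjusted p = 3.99e-18, and adjusted p = 0.0156 with an estimated correlation. Fibroblast markers (7 rose and 1 fell of 13 measured, median 1.68) moved with them (adjusted p = 0.00235, and adjusted p = 0.175 with an estimated correlation). Keratinocyte differentiation genes (0 rose and 12 fell of 17 measured) had adjusted p = 5.3e-11, and adjusted p = 0.0362 with an estimated correlation. In all, 6772 of 14204 genes passed, 3413 higher and 3359 lower in CD44high, and 5358 higher and 2104 lower with library totals. AR (4.03 ± 0.69, adjusted p = 5.77e-05) and TERT (4.24 ± 0.30, adjusted p = 3.36e-10) passed this test although each was high in the CD44high cells of 1 line alone.

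Between 104Med and CD44low, the genes called in HMLER and in HCC38 shared more members than independent lists of their sizes would. Of 11828 genes tested in both lines, 770 were higher in 104Med of both against 514.8 expected (2055 and 2963 called, odds ratio 2.071, Fisher's exact test p = 2.36e-43). For genes lower in 104Med, 1059 were shared against 657.1 expected (2554 and 3043 called, odds ratio 2.603, Fisher's exact test p = 1.44e-87). Genes are not independent replicates, so these p-values describe the lists. Of the 2732 genes called in both lines, 1829 went the same way and 903 went opposite ways. With library totals, 1933 genes were shared among the higher and 529 among the lower. The called lists changed in size as well, to 4944 higher and 1206 lower in HMLER and 4338 higher and 3046 lower in HCC38. No expected number was computed for lists of these sizes, so 1933 and 529 do not show more or less sharing than 770 and 1059.

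The difference between the lines in the 104Med against CD44low change was tested as an interaction, written as the HMLER log2 fold change minus that of HCC38. VIM and CD24 changed in the same direction in both lines by different amounts: VIM rose more in HCC38 (difference -1.43 ± 0.31, adjusted p = 0.00113), and CD24, a surface glycoprotein gene, fell more there (difference 1.94 ± 0.27, adjusted p = 8.48e-06). EPCAM fell more in HMLER (-3.40 ± 0.43, adjusted p = 3.4e-06) and KRT5 fell more in HCC38 (2.69 ± 0.41, adjusted p = 3.54e-05). TENM2, a teneurin adhesion gene, went from 1776 counts in HMLER CD44low to 16 in 104Med and from 4 to 8511 in HCC38 (-17.57 ± 0.68, adjusted p = 4.51e-13). SULF1, which encodes an extracellular sulfatase, changed the opposite way, higher in HMLER 104Med and lower in HCC38 104Med (13.63 ± 0.67, adjusted p = 4.63e-12). Its counts went from 5 to 1796 in HMLER and from 157 to 4 in HCC38. In all, 5081 of 14204 genes differed between the lines, 2671 with a higher and 2410 with a lower fold change in HMLER, and 3463 and 1430 with library totals. The lines were cultured in different media and HMLER is transformed in culture, so line and medium are confounded.

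Last, the luminal lines MCF7 and ZR751 (n = 3 each) were compared with the CD44low groups of HMLER (n = 3) and HCC38 (n = 2). ESR1, the oestrogen receptor α gene, had 2 counts over the CD44low libraries, a ratio of 3977 (95% counting interval 1101 to 32848). The luminal factor genes FOXA1 (7.45 ± 0.14, adjusted p = 1.58e-15) and GATA3 (5.06 ± 0.15, adjusted p = 5.09e-14), the oestrogen-induced gene TFF1 (11.57 ± 0.36, adjusted p = 7.58e-14) and AR (9.55 ± 0.37, adjusted p = 1.06e-12) were higher in the luminal lines. CD44 (-5.15 ± 0.12, adjusted p = 7.39e-15), VIM (-6.59 ± 0.27, adjusted p = 2.2e-12) and KRT5 (-10.85 ± 0.36, adjusted p = 1.67e-13) were lower, and EPCAM did not pass (-0.04 ± 0.10, adjusted p = 0.753). Luminal genes (23 rose and 1 fell of 25 measured) and oestrogen response genes (20 rose and 0 fell of 22 measured) had adjusted p = 9.89e-13 and 1.4e-09, and adjusted p = 0.0106 for both with an estimated correlation. Basal genes (0 rose and 24 fell of 26 measured) had adjusted p = 8.04e-10, and adjusted p = 0.0888 with an estimated correlation. Fibroblast markers were lower as well (1 rose and 6 fell of 9 measured, adjusted p = 0.0175, and adjusted p = 0.25 with an estimated correlation). The counts adjusted over the list alone were the same for these lists. In all, 10012 of 14231 genes passed, 4967 higher and 5045 lower in the luminal lines, and 6125 higher and 3760 lower with library totals. Each side holds 2 lines, so these p-values do not cover the variation between lines, and the media differed for HMLER.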

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

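The results in this part drew attention because the change from CD44low to 104Med differed between HMLER and HCC38, by an interaction test in edgeR with Benjamini-Hochberg adjustment; the tests of depth and of swapped libraries for TERT, and of cells of MCF7 or ZR751 for AR, were chosen only after those results were seen. Differences are the HMLER log2 fold change minus that of HCC38, and where a group held 3 counts or fewer the adjusted p is given in place of a fitted difference. Samples per group were 3, or 2 for HCC38 CD44low.

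TERT differed between the lines by 8.463 ± 0.73 (adjusted p = 1.7e-08): it rose from 20 to 13455 counts in HMLER, in all 3 libraries, while the HCC38 groups held 15 and 31. Lower depth of the CD44low libraries is argued against, since the mean CD44high level would have given at least 1934 TERT counts in each. Their totals ran from 11558469 to 18417164, against 14854599 to 19299296 in 104Med and 4915395 to 17180817 in 104High. A swap of single libraries between the HMLER groups is argued against as well, since the lowest CD44high library stood 234.9 times above the highest CD44low library. The values of 1934 and 234.9 rest on the same TERT counts that drew attention to the gene. What stays open is whether the CD44low cells lack active transforming constructs: of 9 measured genes of RAS-MAPK output, 6 were lower in CD44low than in 104Med and 7 than in 104High (camera, adjusted p = 0.168 for both). For the SV40 early region, the median p53 target of 23 was higher in CD44low by 0.4817 against 104Med (camera, adjusted p = 0.168) and by 0.1744 against 104High (adjusted p = 0.494), too small a shift to decide. HMLER cells that never carried or had silenced the TERT construct may thus account for the CD44low level, as a hypothesis that cannot be told apart here from regulation with the CD44 state.

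AR had an adjusted p = 0.0327 for the difference between the lines, with counts of 1 and 2 in HMLER CD44low and 104Med and of 4 and 885 in HCC38, and the call was lost without HMLER CD44low replicate 2 (adjusted p = 0.962), HCC38 CD44low replicate 1 (0.0582) or HMLER 104Med replicate 3 (0.0506) and with all libraries in 1 fit (0.0707), over a range of 3.06e-11 to 0.962. Cells of MCF7 or ZR751 in the HCC38 CD44high libraries are argued against: a mean AR level of 18.53 CPM would bring 52.7 or 22.93 CPM of ESR1, and the highest ESR1 level was 0.00275 times the lower of these. Cells of another origin stay open: a level under 0.5 CPM, set beforehand as evidence against them, was met by a highest library value of 0.0995 CPM, but 1 gene alone (PLAA) was near 0 in HCC38 CD44low and abundant in all other lines, too few for a set. For androgen-responsive genes in HCC38, a list median at or below 0 in both CD44high groups was set beforehand as evidence against a rise with AR. That was met, with medians of -0.4934 in 104Med (8 rose and 15 fell of 31) and -0.1204 in 104Low. A stricter rule than the one set beforehand, bootstrap intervals over genes wholly below 0, was not met (-0.872 to 0.213 and -1.6 to 0.279). Members went both ways, so the question was not settled. The list's test gave adjusted p = 0.0885 and 0.133, over ranges of 0.0284 to 0.521 and 0.0349 to 0.707. Downward calls came in a fit of all libraries at 0.0284 and 0.0349 and, in 104Med, with limma on log2(CPM + 1) at 0.0443 and without the filter at 0.0323. Activity of the receptor and its ligand in the medium were not tested.

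Among genes named in every comparison, EPCAM fell more in HMLER (-3.397 ± 0.43), as did KRT14 (-7.112 ± 0.78), which held 29 and 24 counts in HCC38. CD24 (1.944 ± 0.27) and KRT5 (2.687 ± 0.41) fell more in HCC38. VIM rose more in HCC38 (-1.425 ± 0.31). ZEB1 (adjusted p = 0.000601) went from 0 to 1228 counts in HMLER and from 14 to 769 in HCC38. FOXA1 differed by 2.505 ± 0.73 (adjusted p = 0.0103), with 13 and 21 counts in HMLER and 81 and 24 in HCC38, and missed the threshold with limma on log2(CPM + 0.1) (adjusted p = 0.0576, range 0.00117 to 0.0576). GATA3 differed by 1.145 ± 0.32 (adjusted p = 0.00723) and missed it without HCC38 CD44low replicate 1 (adjusted p = 0.0679, range 0.00155 to 0.0679).

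Several genes moved in opposite directions in the lines. The epithelial sodium channel gene SCNN1B (adjusted p = 5.01e-10) rose from 168 to 4163 counts in HMLER and fell from 2722 to 2 in HCC38. FRMD3 (difference 14.83 ± 0.63), SULF1 (13.63 ± 0.67) and SPTB (12.7 ± 0.84) rose in HMLER, by 7.53, 7.77 and 5.63, and fell in HCC38, with log2 fold changes of -7.24, -5.81 and -6.99. In HMLER their counts went from 4 to 1201, 5 to 1796 and 4 to 335. In HCC38 they went from 407 to 4, 157 to 4 and 550 to 7. The size of these differences thus rests on few counts in HMLER CD44low and HCC38 104Med. STAC2 (adjusted p = 3.11e-10) went from 1 to 770 counts in HMLER and from 996 to 52 in HCC38. TENM2 (difference -17.57 ± 0.68) fell from 1776 to 16 counts in HMLER and rose from 4 to 8511 in HCC38.

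Other genes changed in a line where the other had few counts. MSTN (adjusted p = 0.00506) and GDNF (adjusted p = 8.64e-09) rose in HCC38 from 0 to 5413 and 1808 counts, with 3 and 1 MSTN counts and 16 and 11 GDNF counts in HMLER CD44low and 104Med. The filaggrin gene FLG (adjusted p = 0.00112) went from 0 to 501 counts in HCC38 and from 5 to 0 in HMLER. BRINP2 (adjusted p = 0.00688) fell from 527 counts to 0 in HCC38, with 0 and 1 in HMLER. PTPRD (adjusted p = 0.000285) and PRSS3 (adjusted p = 0.00156) fell from 224 and 1609 counts to 0 in HMLER, while HCC38 held 0 and 3 PTPRD counts and 2 and 2 PRSS3 counts. In the other line these genes held at most 16 counts in a group. Some calls were lost under an alternative, and the cause was not tested: BRINP2 without HMLER 104Med replicate 1 (adjusted p = 1, range 5.54e-13 to 1), FLG without HMLER CD44low replicate 1 (1, range 3.07e-12 to 1), PRSS3 without HCC38 104Med replicate 3 (1) and with the replicate block (1, range 9.13e-14 to 1) and MSTN without HMLER CD44low replicate 3 (0.0873, range 2.83e-10 to 0.0873).

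By list, basal genes fell more in HMLER (median difference -1.63, 6 rose and 16 fell of 26 measured by the test of the difference, adjusted p = 0.00219). Androgen response genes (0.49, adjusted p = 0.0296), TGF-beta genes (1.37, adjusted p = 0.0288) and endothelial markers (2.81, adjusted p = 0.0223) had higher median fold changes in HMLER. Members went both ways in the androgen list (15 rose and 8 fell of 32 measured, 15 and 9 adjusted over the list alone). The same held for the TGF-beta list (12 and 4 of 20, 13 and 4 over the list alone). Of the endothelial markers 2 rose and 0 fell of 8 measured. Of the 12 on the list, 1 reached a mean of 1 CPM in HCC38 104Med and 2 in HCC38 CD44low. In HMLER 104Med and CD44low 3 and 2 did, so the median difference of this list rests largely on genes of low level. With an estimated correlation the adjusted p = 0.226 for the basal and androgen lists, 0.515 for TGF-beta and 0.181 for endothelial markers. The androgen call was also lost without HCC38 104Med replicate 1 (0.0684), HCC38 CD44low replicates 1 (0.194) and 2 (0.183) or HMLER 104Med replicate 2 (0.0523), the TGF-beta call without HCC38 104Med replicate 1 (0.0524) and the endothelial call without HMLER 104Med replicate 1 (0.0522). Over all alternatives these adjusted p-values ranged from 0.00998 to 0.226, 0.00998 to 0.515 and 0.00939 to 0.181.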

How the results depend on the processing

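The comparisons with limma on log2(CPM + 1), DESeq2, library totals in place of TMM and mitochondrial genes left out were chosen only after the data had been seen. Under every alternative not named in this part, each total of called genes stayed within 1.5 times its reported value. For HMLER 104Med against 104High the count rose from 1348 to 2455 when all 23 libraries shared 1 fit, while that of HCC38 104Med against 104Low fell from 1840 to 1202 in the fit of all libraries. With library totals the genes higher in 104Med of both lines numbered 1933 in place of 770 and those lower in both 529 in place of 1059, from called lists that changed in size as well. The median log2 fold change of all genes lay between -0.0286 and 0.0155 with TMM. With library totals it was 0.487, 0.207 and 0.304 for HMLER 104Med and 104High against CD44low and 104Med against 104High, 0.151 and 0.189 for HCC38 104Med and 104Low against CD44low, -0.0534 for 104Med against 104Low, 0.305 for the difference between the lines, 0.248 over both lines and 0.245 for the luminal lines. The fold changes in the text are relative to the TMM scale, and the cause of the gap between the scales was not tested. By direction, some counts moved by over 1.5 times as well, besides those with library totals given with each comparison: in the fit of all libraries the genes higher in HMLER 104Med numbered 3458 against CD44low (from 2236) and 1147 against 104High (from 389, with 1308 lower), and those higher in HCC38 104Med than in 104Low 506 (from 830). Without the filter 627 genes were higher in HMLER 104Med than in 104High. Leaving out 1 library at a time, the totals ranged from 3829 to 4973 and from 3105 to 4160 for HMLER 104Med and 104High against CD44low, from 624 to 1723 for 104Med against 104High, from 4908 to 7513 and from 4758 to 7825 for HCC38 104Med and 104Low against CD44low, from 815 to 3737 for 104Med against 104Low, from 3847 to 5258 for the difference between the lines, from 5343 to 6874 over both lines and from 9021 to 10242 for the luminal lines. The shared genes ranged from 557 to 805 (higher) and from 819 to 1155 (lower). Where this left HCC38 CD44low with 1 library, that library was assumed to vary like the other groups. Among genes the naming rule gave, 4 called values changed sign with limma on log2(CPM + 1): OAS1 (from 2.681 to -0.08253) and RHCG (from -4.652 to 0.05764) for the difference between the lines, KDR over both lines (from -1.308 to 0.7171) and SNAI1 in the luminal lines (from 0.8539 to -0.1684), and the cause was not tested. With DESeq2, 771 named results stayed on the same side of the threshold, 6 lost and 3 gained a call, with library totals 739, 34 and 7, with median-ratio scaling 776, 4 and 0, and without mitochondrial genes 776, 3 and 1. Without the filter they were 772, 3 and 5, in the fit of all libraries 762, 13 and 5, and with limma on log2(CPM + 0.1) 771, 7 and 2. Of 180 list results, 49 lost their call with an estimated correlation. Small changes were often missed in the simulations, which took the depth and spread of these libraries. Of 1.5-fold changes, 7.46% were recovered for HMLER 104Med against CD44low (12096 genes), 26.9% for HCC38 (13329 genes) and 4.48% for the difference between the lines (13485 genes, with 7.69% false calls). Far fewer genes were changed in the simulations than the 4969 and 7148 called in HMLER and HCC38. That makes the adjusted threshold stricter there, so these shares may understate recovery in the data. The part of depth was not separated from that of spread.

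The labels do not say that replicate numbers pair the libraries, and not every same-number pair deviated together, so they were not treated as pairs. Libraries with the same number had correlations of their deviations from -0.0657 to 0.4 in HMLER (5 of 9 over 0.1, against 2 of 18 with different numbers), from -0.0889 to 0.26 in HCC38 (4 of 7, against 1 of 14) and from -0.0504 to 0.104 in the fit with the luminal lines (1 of 15, against 1 of 30). Correlations over 0.1 were thus more frequent with the same number within HMLER and HCC38, up to 0.4 for HMLER 104Med and CD44low replicates 2, and a shared factor in part of the libraries stays open. These counts are not independent in any fit, since each deviation is taken from the mean of its own group. In HCC38 the deviations of the 2 CD44low libraries mirror each other. A correlation of 0.152 of 104Med replicate 2 with CD44low replicate 2 thus came with -0.152 for CD44low replicate 1. As a hint from the data, not the design, not every library correlated best with its own number. HMLER 104High replicate 3 stood at -0.0657 with CD44low replicate 3 and 0.256 with CD44low replicate 1. For HMLER 104High replicate 1 the values hardly differed, 0.0743 with 104Med replicate 1 and 0.0766 with 104Med replicate 2. A shared factor need not show in every pair, so this does not exclude one. With the number as a block, HMLER 104Med against 104High gave 2131 called genes (from 1348), 682 higher and 1449 lower (from 389 and 959), and HCC38 104Med against 104Low 2069, and of the named results 772 stayed on the same side of the threshold, 4 lost and 4 gained a call.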

Other observations

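Among the results in this part, the count of calls without mitochondrial genes was chosen only after the data had been seen. Between HMLER 104Med and 104High, stem cell markers (0 rose and 5 fell of 12 measured, 1 and 6 adjusted over the list alone, median -0.78) had adjusted p = 0.00512, and the Wnt list (0 rose and 7 fell of 16 measured, 1 and 8 adjusted over the list alone, median -0.74) adjusted p = 0.00409, each with adjusted p = 0.291 with an estimated correlation. LGR6, an R-spondin receptor gene (-2.44 ± 0.26), and DKK1, which encodes a secreted Wnt inhibitor (-1.85 ± 0.27), fell. Cholesterol synthesis genes (1 rose and 6 fell of 22 measured, 1 and 9 adjusted over the list alone, median -0.37) had adjusted p = 0.0189, and adjusted p = 0.428 with an estimated correlation. HMGCR, the rate-limiting enzyme gene of that pathway, changed by -1.23 ± 0.23. Against HMLER CD44low, steroid enzyme genes (7 rose and 1 fell of 13 measured, 7 and 1 adjusted over the list alone, median 0.60) were higher in 104Med (adjusted p = 0.014, and adjusted p = 0.172 with an estimated correlation), among them AKR1C2, a ketosteroid reductase gene (4.48 ± 0.27), and CYP19A1, the aromatase gene, at least 30.5-fold higher.

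In HCC38, TGF-beta genes of 104Med against CD44low went both ways, 4 rose and 13 fell of 20 measured (4 and 13 adjusted over the list alone), with a median of -0.94, adjusted p = 0.0141 and adjusted p = 0.384 with an estimated correlation. SERPINE1, the plasminogen activator inhibitor 1 gene, rose by 5.62 ± 0.36, while PMEPA1, which encodes a membrane protein that limits TGF-beta signals, and INHBA, an activin subunit gene, changed by -4.32 ± 0.19 and -4.21 ± 0.27. Steroid receptor genes (3 rose and 7 fell of 12 measured, median -0.58, adjusted p = 0.419) did not pass as a list, although the mineralocorticoid receptor gene NR3C2 changed by -4.81 ± 0.52. Proliferation genes (7 rose and 0 fell of 30 measured, 11 and 0 adjusted over the list alone, median 0.26) were higher in HCC38 104Med than in 104Low (adjusted p = 0.000804, and adjusted p = 0.572 with an estimated correlation). Over both lines, hypoxia and glycolysis genes (15 rose and 1 fell of 20 measured, 16 and 1 adjusted over the list alone, median 0.60) were higher in CD44high cells (adjusted p = 0.00236, and adjusted p = 0.149 with an estimated correlation), with EGLN3, an oxygen-sensing hydroxylase gene, up by 1.37 ± 0.30, although the libraries of the 2 sides overlapped. Inflammatory cytokine genes (1 rose and 12 fell of 16 measured, median -4.38) were lower in the luminal lines than in the CD44low groups (adjusted p = 9.86e-05, and adjusted p = 0.0888 with an estimated correlation), with IL24, an interleukin gene, as the member that rose (6.14 ± 0.65).

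The mitochondrial share of counts was higher in CD44low cells of both lines, 27.6% against 8.04% in 104Med of HMLER and 17.1% against 10.3% in HCC38. Most calls in HMLER 104Med against CD44low did not rest on these counts through scaling, since 4687 of 4969 called genes (a share of 0.943) kept their call and direction without them. The balance did move, from 2236 higher and 2733 lower to 2541 and 2523. Carry-over of RNA without poly(A) tails stays open and cannot be told apart from a cell difference: replication-dependent histone genes, which lack such tails, were higher in CD44low by a median of 0.41 over 17 genes in HMLER (quartiles -0.355 and 1.22) and 0.804 over 38 in HCC38 (quartiles 0.289 and 1.21). More mitochondrial RNA in CD44low cells, or stress of the cells, may account for the shares as well, and neither was tested.

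HMLER 104Med replicate 3 lay toward 104High from the other 104Med libraries: over 1544 genes called between 104High and the other 104Med libraries, it stood a median share of 0.369 of the way to 104High (quartiles 0.164 and 0.581, an interquartile range of 0.417), as a library holding some cells of the 104High kind may. Of these genes, 158 had a share under 0 and 36 a share over 1. By the same measure replicates 1 and 2 stood at medians of -0.0272 over 624 genes and 0.00488 over 658 genes. For these 2 the other 104Med libraries include replicate 3, so their medians are not a clean baseline for 0.369. Choosing genes called with the other libraries may itself raise the share, and by how much was not tested. The mitochondrial share of counts in replicate 3 was 3.046%, against 11.56% and 9.529% in replicates 1 and 2. In 104High replicates 1, 2 and 3 it was 7.909%, 9.881% and 6.576%. A mix of cells of the 2 groups alone would not give so low a share, so replicate 3 differed in some further way.

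Other splits of the libraries were counted for each comparison with at least 3 libraries a side. The 10 splits of 6 libraries are too few for a share under 0.05: the real split gave 4969 called genes for HMLER 104Med against CD44low (highest other 0), 4066 for 104High against CD44low (0), 1348 for 104Med against 104High (1) and 1840 for HCC38 104Med against 104Low (0). For CD44high against CD44low over both lines, 1 of 50 splits, the real one and others drawn at random, gave as many as 6772 genes (highest other 4), a share under 0.05. Random splits join libraries of groups that differ, which widens the spread within a side and by itself gives few calls. The replicates may also be technical, so the share does not exclude chance, and it does not cover variation between lines. For the luminal lines 1 of 50 gave as many as 10012 (highest other 401), but lines, not libraries, are the units there, and 4 lines are too few for a share under 0.05.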
